A study of Mus musculus with 3 samples.

How the data were processed

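RNA of 3 tissue pairs was compared on 2-colour Agilent mouse arrays. Per the labels' protocols, 500 ng of total RNA isolated with a Qiagen kit was amplified and labelled with Cy3 or Cy5 with the Agilent linear amplification kit for low RNA input. Per the sample records and the file headers, the scans were read with Agilent Feature Extraction 8.5.1.1. Scanner files were analysed for the liver and stomach arrays, and the lung array's scanner values were not analysed here. Each organ had 1 array, so groups were of 1 sample, with no replicates, no dye swap and no pooling stated.

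Each array held 43790 spots, of which 41534 were gene spots, 1942 positive controls and 314 negative controls. Per the file headers, the authors' deposited intensity columns hold the mean pixel intensity of each spot and the median intensity of its local background in both channels, without normalization, and processed intensities corrected for background with a spatial surface and for dye with a linear and lowess fit. The deposited log10 ratio is log10 of red (Cy5) over green (Cy3) processed intensity, with an error from the scanner software's error model, per the file headers. The deposited p-value of each spot tests that ratio against 0 under the same error model, per the file headers, and covers the measurement error of 1 spot only. The genome build of the probe coordinates is not given in the sources used here.

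The authors' deposited table of differentially regulated genes stacks 6 lists, up and down for each organ, whose values are the log10 ratio of red over green, per its column notes. Up lists held only Cy5-high spots and down lists only Cy3-high spots. For liver (518 and 433 spots) and stomach (1660 and 1382 spots), all values equalled the ratio of the same spot number in the scanner file within 0.002, the largest scanner p-values were 0.0099 to 0.0100, and the smallest fold was 1.35. The lung lists (2288 and 4064 spots) started at 2-fold. Lung spot numbers were taken to name the same design: the signals of the lung up list correlated with the liver array's brightness at the same spots (Pearson r = 0.610 on log2 values) against at most 0.077 in size over 1000 shuffles. The table's signal columns change order within the lung down list and were not used there. In the lung up list the channel 2 over channel 1 signal gave the listed ratio at all 2288 spots, and these signals were used only for this match and for the comparison of lung with stomach signals.

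The tables and labels disagree on direction, as stated with the results. The design written beforehand took the tumour as Cy3, as the labels say; values are reported by channel instead, which leaves every size and count as planned and turns only the name of the direction.

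From the scanner files, backgrounds were corrected with normexp (offset 50) and ratios normalized within each array by loess in limma 3.58.1 under R 4.3.3, with control spots at weight 0 in the loess fit. Control spots and spots flagged as outliers for non-uniformity or population were then left out. Probes had to be well above background in at least 1 channel and not saturated in both. Spots of 1 probe were averaged, and a gene's value was the mean over its measured probes; probes of a gene disagreed by the SD given with the results. The offset pulls ratios of dim genes towards 0. Later steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

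Gene names followed current symbols, from a RefSeq table of assembly GRCm38.p6 used for names only. Of 41174 probes, 23082 were named by accession, 6582 by a current symbol and 3060 by a synonym, together 79.5%; 8450 kept the file's name. In the intestinal epithelium list, the symbol Si was matched to Pmel, a pigment cell gene, so that list can hold a gene that is not intestinal. No column of per-sample values was left unused for want of a sample.

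With 1 array per organ no test was made. Genes were counted by size, at a log2 ratio of at least 1 in either direction. Overlaps of lists were set beside the number that independent lists of the same lengths would share, without matching on brightness. For 32 gene lists fixed before the data were examined, the median was placed among 10000 random lists of the same size, matched over 20 bins of brightness; its percentile describes these arrays and is no test between conditions. Errors given with genes are the SD between probes or, with 1 probe, the scanner software's error on the log2 scale, and cover measurement only. Where a gene was not well above background in the dimmer channel on any probe, its fold is given as at least the ratio of the bright channel to the higher of the dim signal and the lowest signal well above background in that channel, after loess and scaling of brightness between arrays; such a bound is open to dye bias.

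The named genes followed a rule fixed beforehand, and "highest" and "lowest" in the results refer to genes that pass it: per array, the 12 highest and 12 lowest genes with a symbol whose probes all passed 2-fold in the same direction and whose scanner ratio did too (26 and 12 genes qualified in liver, 159 and 236 in stomach); the 5 highest and 5 lowest genes past 2-fold on both arrays; up to 4 members per list of the largest size; Myc, Trp53 and Ctnnb1 whatever their value; and the 5 highest and 5 lowest named lung genes of the authors' deposited table. Some further members of the same lists are named in the text and were chosen after their values were seen. Some genes that the rule would name are not reported here.

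Alternatives fixed beforehand were the scanner software's own ratios, a normexp offset of 16, no background correction, median centring without loess, no filter on dim probes, a filter for both channels, the brightest probe per gene, a 3-fold threshold and an added scanner p-value under 0.01.

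The steps were tested on simulated data made from each array's signal levels, with 200 genes changed. For the liver array's comparison, run on 25856 genes, 34.4% of 93 genes changed by 1.5 log2 units and 75.3% of 89 changed by 3 passed 2-fold, with median recovered sizes of 0.85 and 1.56, and none of 25674 unchanged genes did. For the stomach array's comparison, run on 25561 genes, the shares were 37.4% and 75.3%, the recovered sizes 0.90 and 1.75, and none of 25381 unchanged genes passed. Of unchanged lists, 6.0% in liver and 3.0% in stomach lay outside the central range. Among changed genes brighter than the median gene, sizes of 1.5 were recovered as 1.06 in liver and 1.09 in stomach, with 61.2% and 66.7% past 2-fold, and sizes of 3 as 2.21 and 2.19. In the simulation, ratios were thus understated, and counts at 2-fold were low. No dye bias of probes was simulated, so the lack of unchanged genes past 2-fold does not carry over to the real arrays.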

Results

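Gene expression was measured in tumours of mice that carry a transgene for activation-induced cytidine deaminase (AID). The series names 3 samples, 1 per organ: a liver tumour beside nontumour liver of the same mouse, a stomach tumour beside nontumour stomach of the same mouse, and a lung tumour of a transgenic mouse beside normal lung of a wild-type mouse. Each was a 2-colour hybridisation, with the tissues of a pair labelled with Cy3 and Cy5 and read from the same array. Scanner values were analysed for the liver and the stomach array; for lung, only the authors' deposited table of differentially regulated genes was used here. There were no replicates and no arrays with exchanged dyes, so no difference below has a replicate check, no p-value is given for it, and the number of arrays limits the precision.

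The direction of the ratios was not settled by the sources. The sample labels put the tumour in Cy3, whereas the authors' deposited table lists genes brighter in Cy5 under its headings for genes up in the tumour. Values are therefore given by channel, as log2(Cy5/Cy3), and genes are called Cy5-high or Cy3-high. By the authors' headings, and by the series' design text that points to those lists, Cy5 was the likely tumour channel; by the dye labels it was the nontumour tissue, and every sign would turn.

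The median gene spot of the liver array had a raw signal of 180 in Cy3 and 152 in Cy5, against medians of 127 and 67.7 over the negative control spots. On the stomach array these values were 171 and 163, against 119 and 68.4. Gene spots well above background made up 84.1% in Cy3 of the liver array, 82.3% in Cy3 of the stomach array and 88.8% in Cy5 of the stomach array. Probes printed at several places on the array had a median standard deviation (SD) between spots of 0.05 log2 units on the liver array and 0.06 on the stomach array, over 40 probes each. Different probes of a gene differed more, with a pooled SD of 0.18 over 8149 genes in liver and 0.26 over 8053 genes in stomach.

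The comparison of liver tumour with nontumour liver asked which genes differ between the tissues of a mouse. Afp, Igf2 and Ly6d were the most Cy5-high of the named genes, and genes of mature hepatocytes lay to the Cy3 side. Afp, the fetal serum protein used as a liver tumour marker, was 25.8-fold brighter in Cy5 (log2 ratio 4.69, scanner error 0.44, 1 probe on chromosome 5 at 90479870 to 90479929). Igf2, a fetal growth factor, was 11.6-fold brighter in Cy5 (3.53, SD 0.38 between 2 probes), and H19, the noncoding RNA from the same imprinted region, was 3.17-fold brighter (1.66, SD 0.14 between 2 probes). Ly6d, a cell surface protein, was 10.1-fold brighter in Cy5 (3.33, scanner error 0.32).

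Over all 25601 genes measured on the liver array, 39 were at least 2-fold brighter in Cy5 and 18 at least 2-fold brighter in Cy3. After Afp, Igf2 and Ly6d, the highest of the named genes were Sult2a2 (2.13, SD 1.26 between 2 probes), a sulfotransferase, and the carboxylesterase Ces1g, listed as Ces1 on the array (3.89-fold, SD 0.10 log2 units between 2 probes). Bex4 had a ratio of 1.68 and Serpina6, which carries corticosteroids in blood, 1.68. Gsn, which severs actin filaments, followed at 1.60, Igfbp6 at 1.51, Amn at 1.49 and Gstm2, a glutathione transferase, at 1.37. Their scanner errors lay between 0.20 and 0.50.

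On the Cy3 side of the liver array, Tmem54 had the lowest ratio of the named genes (-1.59, scanner error 0.59), followed by the secreted protease inhibitor Slpi (-1.38, error 0.20). Several products of adult liver came next. The major urinary protein genes Mup4 and Mup5 had ratios of -1.34 and -1.24, Cyp2f2 -1.33, the retinol carrier Rbp4 -1.33, the apolipoprotein Apoa5 -1.21 and Itih1 -1.08. Selenbp1 and Selenbp2 both had -1.16, Wfdc15b -1.14 and Id1, a repressor of differentiation genes, -1.12. Mup, Cyp, Gst and Selenbp genes have close relatives whose transcripts the probes could share, so their assignment to a family member is uncertain.

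By list median, glutathione and antioxidant genes (0.26) and interferon response genes (0.24) lay above the fetal liver and liver tumour markers (0.16). Of 21 measured fetal liver and liver tumour markers, 4 were at least 2-fold Cy5-high and none Cy3-high, and the list's median lay above 10000 random lists matched on brightness. Afp, Igf2, Ly6d and H19 were the 4 members. Of 27 hepatocyte function genes on the design, 23 were measured on the liver array, and the others did not pass the spot filters. None of the 23 reached 2-fold, but 19 had ratios below 0 and the median was -0.28 (percentile 0.00). Spots saturated in 1 channel only were kept, and their effect on this list was not tested. Tdo2, which opens the ring of tryptophan, had -0.97, transferrin (Trf) -0.53 and transthyretin (Ttr) 0.53. The 26 genes for cytochrome P450 enzymes and bile acid synthesis had a median of -0.13 (percentile 0.17), with 1 member 2-fold Cy3-high (Cyp2f2) and 1 Cy5-high (Cyp2a5, 1.26). Among their smaller values were Cyp3a11 at -0.52 and Nr0b2, the bile acid regulator SHP, at -0.47. Both medians turned sign, to 0.08 for hepatocyte function and 0.07 for the P450 list, when the array was centred on its median without a loess curve, although both stayed at or below percentile 1.03.

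The median of the glutathione and antioxidant genes on the liver array was shifted to the Cy5 side, above the random lists, with 2 of 24 genes 2-fold Cy5-high, Ces1g and Gstm2, and 7 below 0. The glutathione transferases Gsta2 and Gsta1 followed at 0.97 and 0.95. The median of the interferon response genes also lay above the random lists, and although none of 26 reached 2-fold, 22 lay above 0. The largest were Igtp at 0.65, Cxcl10 at 0.54, Iigp1 at 0.52 and Mx2 at 0.46. Extracellular matrix and fibroblast genes had a median of 0.12 (percentile 99.92), with Col1a2 at 0.66, Dcn at 0.64, Pdgfrb at 0.63 and Fn1, which hepatocytes also make, at -0.64. Endothelial genes had a median of 0.12 (percentile 99.83, 17 of 20 above 0), led by Vwf at 0.37. Intestinal epithelium genes had a median of 0.10 (percentile 97.81), with Krt20 at 0.71 and Fabp1, also a liver gene, at 0.62. Under at least 1 alternative the list lay inside the central 95% of random lists, with a lowest percentile of 83.91.

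Lists for other cell types and processes lay within the central 95% of random lists on the liver array, and some of their medians turned sign under another setting. The medians were 0.05 for cell cycle genes, -0.01 for T cells, 0.01 for B cells and plasma cells, and 0.03 for macrophages and neutrophils, where the neutrophil proteins S100a9 and S100a8 stood at 0.87 and 0.80. They were 0.04 for MHC class II and antigen presentation, 0.06 for Wnt targets, where Ccnd1 (1.11) was 2-fold Cy5-high and Glul, a marker of liver cells with active Wnt signalling, had 0.66, and 0.04 for p53 targets. Sex-biased liver genes went both ways around a median of -0.06, with Sult2a2 and Cyp2a4 (1.07) Cy5-high and Mup4, Mup5 and Mup1 (-1.15) Cy3-high. Acute phase genes had a median of -0.07, with Lcn2 at 1.14 and Orm3 at 0.76 against Fga at -0.59 and Hp at -0.55. The medians were -0.02 for lipid synthesis, -0.07 for hypoxia and glycolysis, -0.01 for immediate early and heat shock genes, -0.04 for oxidative phosphorylation, 0.06 for ribosomal proteins and -0.01 for base excision and mismatch repair. They were 0.08 for the AID and APOBEC family, 0.08 for the cancer genes and cytokines linked to AID tumours, 0.05 for smooth muscle, 0.002 for skeletal muscle and fat, and -0.04 for red blood cells. Markers of gastric glands, squamous epithelium, exocrine pancreas and lung epithelium had medians of 0.05, 0.01, 0.02 and 0.003. Under at least 1 alternative, cell cycle genes (percentile 98.04), Wnt targets (97.92), the cancer genes and cytokines (99.17), hypoxia and glycolysis (1.73) and sex-biased liver genes (0.10) lay outside that range.

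The size of the liver counts depended on the processing. With the scanner software's own ratios, 540 genes were at least 2-fold Cy5-high and 420 Cy3-high, and these held all 57 of the genes above, but the further 903 genes had a median log2 brightness of 6.14 against 7.14 over all genes, and the scanner software gave a p-value under 0.01 for 4.9% of them. Of the 2-fold genes, 68.4% were Cy5-high here, 56.2% by the scanner software's ratios, 55.8% with the smaller normexp offset and 94.0% with median centring alone.

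The comparison of stomach tumour with nontumour stomach asked the same question in the stomach. Gastric gland products, squamous epithelium genes and smooth muscle genes lay to the Cy3 side, while cell cycle genes and genes of intestinal epithelium lay to the Cy5 side. Chia1, the acidic chitinase of gastric chief cells (Chia on the array), was 38.3-fold brighter in Cy3 (log2 ratio -5.26, SD 0.26 between 2 probes), and Atp4b, the beta subunit of the parietal cell proton pump, was 30.0-fold brighter in Cy3 (-4.91, scanner error 0.41, 1 probe on chromosome 8 at 13360529 to 13360588). Clca1, a goblet cell protein listed as Clca3 on the array, was 11.6-fold brighter in Cy5 (3.54, scanner error 0.32, chromosome 3 at 144897653 to 144897712). Mki67, a marker of dividing cells, was 2.89-fold brighter in Cy5.

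Over all 25319 genes measured on the stomach array, 221 were at least 2-fold Cy5-high and 359 Cy3-high. The highest of the named genes after Clca1 were Kcne3, a potassium channel subunit (2.72, SD 0.23 between 2 probes), Lyz1, the lysozyme of Paneth cells (2.52), Krt20, a keratin of intestinal and gastric surface cells (2.41), Slc9a3, the sodium and proton exchanger of the brush border (2.39), and Dmbt1, a secreted mucosal protein (2.38). Msln followed at 2.22, Reg1 at 2.17, the tryptophan-degrading enzyme Ido1 at 2.07, Wfdc18 at 2.06, the brush border protein Vil1 at 2.03 and the antimicrobial lectin Reg3b at 1.98. Scanner errors of these genes lay between 0.23 and 0.34.

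The lowest of the named genes after Chia1 and Atp4b were the intrinsic factor gene Cblif, listed as Gif (-4.53), Pdia2 (-4.43), Lor, a protein of the cornified layer (-4.20), Spink5 (-4.18), the proton pump alpha subunit Atp4a (-4.18, SD 0.19 between 2 probes) and Pgc, a pepsinogen (-4.13). Cox7a1, a muscle form of a cytochrome oxidase subunit, had -4.08, the channel subunit Kcne2 -3.88, Krt4 -3.84 and the fat cell protease Cfd -3.82. Scanner errors lay between 0.35 and 0.50.

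Of 25 measured gastric gland markers, 14 were at least 2-fold Cy3-high and 2 Cy5-high, with a median of -1.07 (percentile 0.00). The Cy3-high members included Chia1, Atp4b, Cblif and Atp4a, and the hormones ghrelin (Ghrl, -3.50) and somatostatin (Sst, -1.93). The Cy5-high members were Gkn3 (1.66) and Tff2 (1.17), a product of mucous neck cells. Of 28 squamous epithelium genes, 20 were Cy3-high and 1 Cy5-high (Ivl, 1.16), with a median of -1.66 (percentile 0.00). Lor, Krt4, Lgals7 (-3.50) and Calml3 (-3.35) were the largest, and mouse stomach has a forestomach lined by squamous epithelium. Of 20 smooth muscle genes, 6 were Cy3-high and none Cy5-high, with a median of -0.73 (percentile 0.00), led by Cnn1 (-2.51), Tpm2 (-2.24), Myh11 (-2.09) and Des (-1.99). These 3 lists lay on the Cy3 side under all 7 other settings of background, normalization, filter and probe choice.

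Cell cycle genes lay on the Cy5 side without exception, with all 27 above 0, 9 at least 2-fold and a median of 0.84, above the random lists. Mki67 (1.53), Tpx2 (1.52), Aurkb (1.32) and Birc5 (1.13) were the largest. Of 22 intestinal epithelium genes, 6 were Cy5-high and 1 Cy3-high, with a median of 0.31, above the random lists. Clca1, Krt20, Vil1, Reg3b and Lgals4 (1.79) were among the former, and the aminopeptidase Anpep (-2.38) was the latter. Glutathione and antioxidant genes had a median of 0.48, above the random lists, with Gsta3 (1.80), Gpx2 (0.92), Nqo1 (0.86) and Gsta4 (0.81). MHC class II and antigen presentation genes had a median of 0.38, above the random lists, with H2-DMb1 (1.08) and Cd74 (1.07) at least 2-fold Cy5-high and H2-Ab1 at 0.90. Lipid synthesis genes had a median of 0.26, above the random lists, with Scd2 (1.43) and Me1 (1.37) 2-fold Cy5-high and the sterol enzyme Sqle at 0.98. Base excision and mismatch repair genes had a median of 0.17 (percentile 99.96), with Rpa1 (0.76), Lig1 (0.62), Exo1 (0.56) and Neil3 (0.56). Members such as Lig1 and Exo1 also serve DNA replication and repair in dividing cells.

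Smaller shifts to the Cy5 side were seen for T cells (median 0.12, percentile 99.75, with Gzma at 0.66, Cxcr6 at 0.59 and Lat at -0.59) and for extracellular matrix and fibroblasts (0.09, percentile 98.45, with Mmp3 at 0.71). Shifts to the Cy3 side were seen for oxidative phosphorylation (median -0.28, percentile 0.07, with Cox6c at -1.19 and Ndufa4 at -1.01), red blood cells (-0.19, 0.35, with Hbb-bt at -1.85), hypoxia and glycolysis (-0.18, 0.52, with Bnip3 at -0.69), exocrine pancreas (-0.15, 0.79, with Pnliprp2 at -3.74 and Clps at -2.68), immediate early and heat shock genes (-0.14, 1.35, with Hspb1 at -1.16 and Egr1 at -1.12), hepatocyte function (-0.14, 0.06, with Apoa1 at -3.24 and Arg1 at -1.25) and endothelium (-0.12, 0.88, with Kdr at -0.87 and Flt1 at -0.67). With median centring alone, the medians turned sign for T cells (-0.05), oxidative phosphorylation (0.44), hypoxia and glycolysis (0.32), exocrine pancreas (0.08), immediate early and heat shock genes (0.17) and endothelium (0.08). Under at least 1 alternative, 8 lists came to lie inside the central 95% of random lists: hepatocyte function (percentile 6.08), T cells (86.70), base excision and mismatch repair (96.22), immediate early and heat shock genes (9.19), exocrine pancreas (6.07), endothelium (5.02), hypoxia and glycolysis (4.72) and extracellular matrix and fibroblasts (97.36).

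The remaining lists lay within the central 95% of random lists on the stomach array, and some of their medians turned sign under another setting. Interferon response genes had a median of -0.10 and went both ways, with Ifi27 at -2.21 and Oas2 at -1.33 against Gbp2 at 1.09 and Cxcl9 at 1.01. Macrophage and neutrophil genes did likewise around 0.06, with S100a9 at -1.93 and Gpnmb at -1.57 against Lyz2 at 1.18, and Wnt targets around -0.01, with Sp5 at 1.09 and Axin2 at 1.02 against Glul at -1.21. Fetal liver and liver tumour markers had a median of -0.07, with Akr1b8 (1.68), the stem cell marker Prom1 (1.52) and Krt19 (1.29) Cy5-high and Cdkn1c (-1.69) Cy3-high. Acute phase genes had a median of 0.05, with Mt2 at -1.97, Hamp at -1.23 and Saa3, not well above background in Cy3, at least 2.44-fold Cy5-high. The medians were 0.10 for p53 targets (Pmaip1 1.09, Gadd45a 0.96), -0.004 for B cells and plasma cells, 0.12 for ribosomal proteins, -0.04 for cytochrome P450 and bile acid genes, 0.06 for sex-biased liver genes, -0.03 for skeletal muscle and fat, and -0.03 for lung epithelium, where Sftpd stood at 1.89. The AID and APOBEC family had a median of 0.08, with Apobec1, the intestinal RNA editing enzyme, at 0.81, and the cancer genes and cytokines linked to AID tumours had a median of 0.001, with Cdkn2b at -0.86, Nfkbia at -0.79 and Ctnnb1 at 0.75. Under at least 1 alternative, interferon response genes (percentile 0.03), lung epithelium (1.81), macrophages and neutrophils (98.53), p53 targets (98.10) and the AID and APOBEC family (98.28) lay outside the central range.

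The stomach counts also depended on the processing. By the scanner software's ratios, 1092 genes were at least 2-fold Cy5-high and 1050 Cy3-high, which held all 221 and 353 of the 359 genes above. The further 1568 genes had a median log2 brightness of 6.23 against 7.20 over all genes, and the scanner software gave a p-value under 0.01 for 20.7% of them. Of the 2-fold genes, 38.1% were Cy5-high here, 51.0% by the scanner software's ratios and 81.2% with median centring alone.

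**Figure D1:**
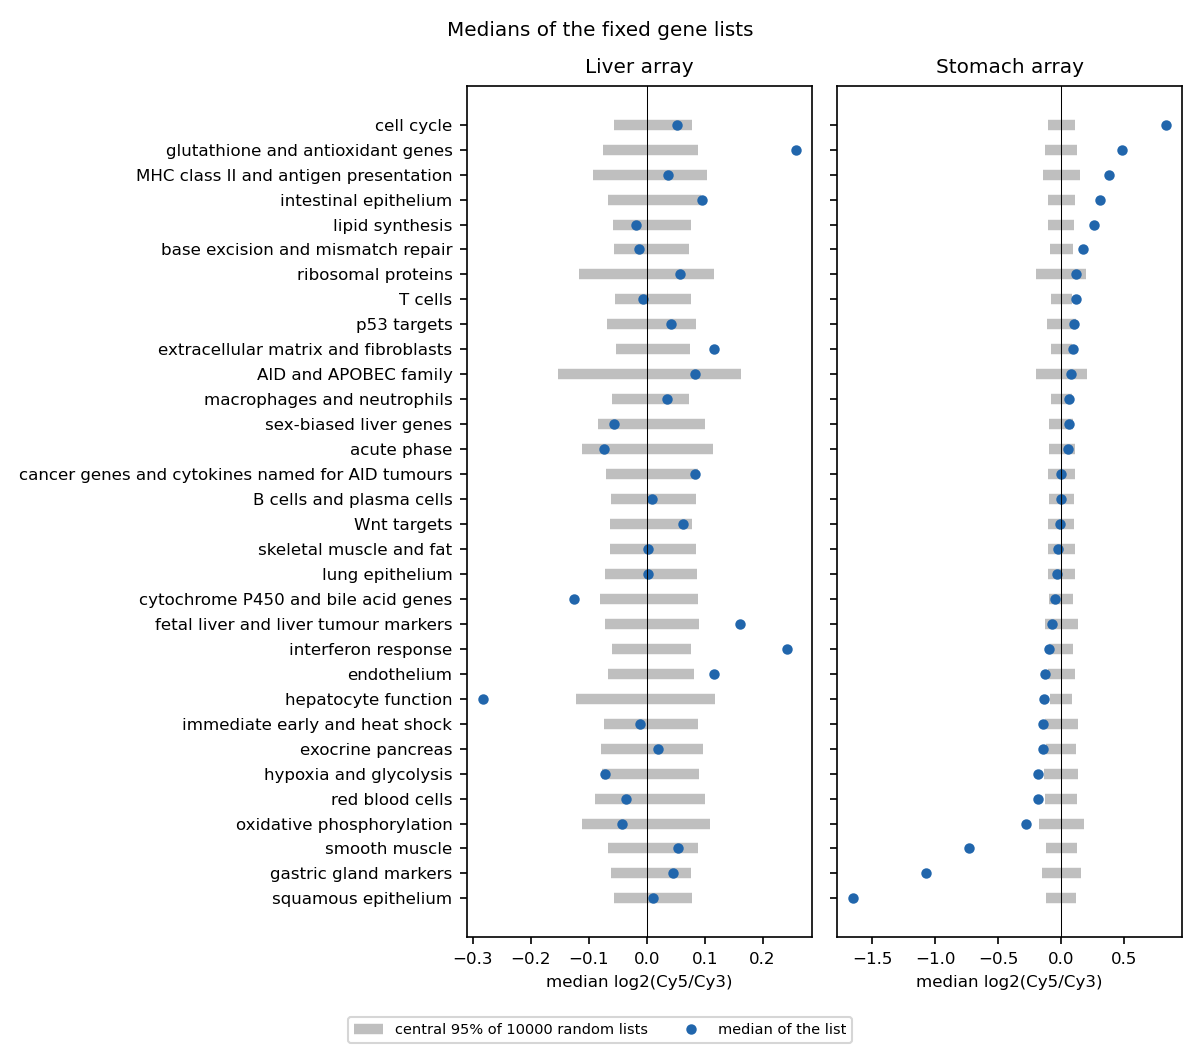
Median log2(Cy5/Cy3) of each fixed gene list (points) on the liver array (left) and the stomach array (right), with the central 95% of 10000 random lists of the same size and brightness (grey bars); the horizontal scales differ. Hepatocyte function lies lowest in liver at -0.28, and squamous epithelium (-1.66), gastric gland markers (-1.07) and smooth muscle (-0.73) lie lowest in stomach, where cell cycle genes lie highest at 0.84.

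The series set the profiles of the organs side by side, and the liver and stomach arrays shared few genes at 2-fold. Of 24763 genes measured on both arrays, 4 were at least 2-fold Cy3-high on both, against 0.25 for independent lists of these lengths. They were Slpi (-1.38 in liver, -2.89 in stomach), Cyp2f2 (-1.33, -2.68), Rbp4 (-1.33, -1.13) and Selenbp1 (-1.16, -1.07). Each of the 4 was under 2-fold on at least 1 array under at least 1 alternative. A transcript without a gene symbol was the 1 gene Cy5-high on both, against 0.32 for independent lists. Opposite directions were not rarer, with 4 genes Cy5-high in liver and Cy3-high in stomach against 0.52, and 4 the other way against 0.16. Cd36, a fatty acid transporter, had 1.28 in liver and -2.33 in stomach, and Mup4 had -1.34 and 1.21.

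Across genes, the log2 ratios of the arrays had a Pearson correlation of 0.10 and a Spearman correlation of 0.20; genes are not independent replicates, and both arrays had the same dye orientation. Of the genes named whatever their value, Myc had 0.15 in liver (SD 0.08 between 3 probes) and -0.43 in stomach (SD 0.22), Trp53 0.11 and -0.28, and Ctnnb1, the gene of beta-catenin, 0.13 (SD 0.42) and 0.75 (SD 0.17 between 3 probes). By the scanner software's ratios the overlap of the arrays was larger in the same direction, with 114 genes Cy5-high on both against 18.6 and 134 Cy3-high on both against 11.7, and the Pearson correlation was 0.23. Opposite directions then held 39 genes Cy5-high in liver and Cy3-high in stomach, against 18.2, and 10 the other way, against 12.01; with no background correction they held 2 and 1.

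**Figure D2:**
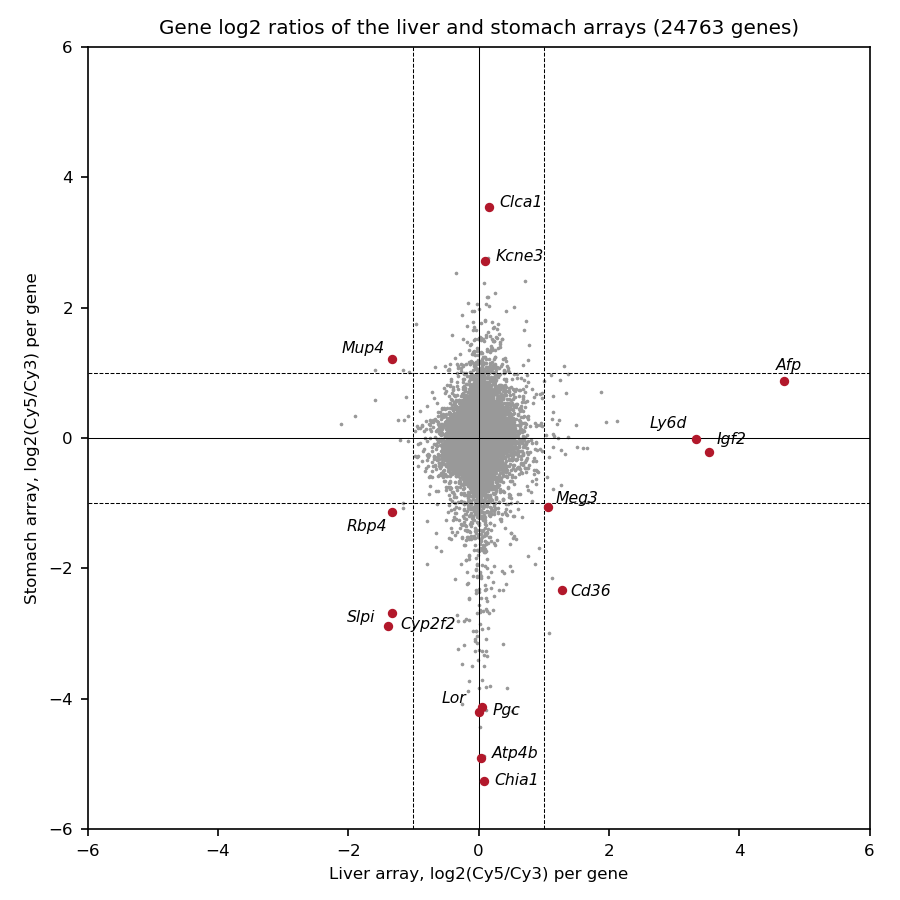
Log2(Cy5/Cy3) of each gene on the liver array (horizontal axis) against the stomach array (vertical axis), 1 point per gene; dashed lines mark 2-fold and red points are named. Afp (4.69) and Igf2 (3.53) stand apart along the liver axis, and Chia1 (-5.26) and Atp4b (-4.91) along the stomach axis, each with a value under 2-fold on the other array.

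For lung, the authors' deposited table compared a lung tumour with normal wild-type lung and lists spots from 2-fold upwards. Genes of the gut lining, of glycolysis and of the hypoxia response were in its up list, and genes of lung epithelium, endothelium, lymphocytes and antigen presentation were in its down list. In the authors' deposited table, Reg1, a secreted protein of regenerating gut and pancreas, was 154.9-fold Cy5-high (log2 ratio 7.27), Ambp 6.41, the neutrophil chemokine Cxcl5 6.21, Reg3b 5.91 and Sprr2f 5.68. The lowest named genes in the authors' deposited table were Cfd (-5.55), the complement component Hc (-5.55), the endothelial receptor Thbd (-5.25), Cyp2f2, a P450 enzyme of airway club cells (-5.15), and S100g (-4.95).

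The authors' deposited table held 2288 lung spots in its up list and 4064 in its down list, or 1858 and 3388 genes at 2-fold after leaving out 26 genes listed both ways. Of all 27673 genes on the array design, 6.71% were listed up and 12.2% down. Whether an unlisted gene was measured is not known for lung, so the shares below are of the genes on the design. In the authors' deposited table, 18 of 22 hypoxia and glycolysis genes were listed up and 1 (Vegfa) down, led by Egln3 (5.12), Ndrg1 (3.72), the glucose transporter Slc2a1 (3.16) and Pgk1 (3.00). Of 24 intestinal epithelium genes, 12 were up and 2 down, with Reg3b, Vil1 (5.07), Tff3 (4.98) and Lgals4 (4.42). The up count includes Pmel (1.21), a pigment cell gene that was matched to the list's symbol Si by mistake. Of 21 fetal liver and liver tumour markers, 10 were up and 3 down, among them Prom1 (3.90), Ly6d (3.75), Krt19 (3.69) and Afp (3.20), and Gpc3 at -3.55.

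Markers of normal lung were in the down list of the authors' deposited table. Of 20 lung epithelium genes, 15 were listed down and none up, led by the surfactant protein Sftpa1 (-4.29), Napsa (-3.99), the alveolar receptor Ager (-3.95) and Slc34a2 (-3.92), and the lung transcription factor Nkx2-1 was among them. Of 20 endothelial genes, 18 were down and none up, with Cldn5 (-3.49), Kdr (-3.26), Egfl7 (-3.01) and Tek (-2.93). Of 26 T cell genes, 18 were down, with Cxcr6 (-3.32), Cd3d (-2.36), Ccl5 (-2.32) and Cd8b1 (-2.30). Of 21 B cell and plasma cell genes, 14 were down, with Jchain (-4.24) and Ighm (-4.14). Of 16 MHC class II and antigen presentation genes, 14 were down, with H2-Eb1 (-2.92) and Ciita (-2.60), and of 20 smooth muscle genes 11 were down. None of these lists had a member in the up list. Interferon response genes were listed down in 14 of 26 cases and up in 2, Oasl1 (3.65) and Irf7 (1.99).

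The other lists had members on both sides of the authors' deposited table or few members in it. Up and down counts were 6 and 0 of 27 cell cycle genes (Cdk1 1.73, Rrm2 1.69), 8 and 1 of 28 squamous epithelium genes, 5 and 5 of 25 gastric gland markers (Anxa10 5.12, Tff2 3.95, Hdc -2.80), 9 and 5 of 27 lipid synthesis genes, 7 and 5 of 24 glutathione and antioxidant genes (Gsta2 3.92, Gstm1 -3.24) and 6 and 3 of 21 p53 targets (Pmaip1 3.39, Cdkn1a 2.61). They were 6 and 2 of 27 hepatocyte function genes, 3 and 7 of 26 P450 and bile acid genes, 4 and 6 of 21 sex-biased liver genes, 1 and 6 of 23 acute phase genes, 4 and 3 of 27 macrophage and neutrophil genes, 6 and 5 of 31 matrix and fibroblast genes, and 4 and 5 of 20 skeletal muscle and fat genes. They were 4 and 8 of 24 Wnt targets, 3 and 8 of 21 immediate early and heat shock genes, 1 and 5 of 26 repair genes, 1 and 4 of 15 red blood cell genes, 2 and 0 of 19 exocrine pancreas genes, 0 and 1 of 26 oxidative phosphorylation genes, and 0 and 1 of 25 ribosomal protein genes. In the AID and APOBEC family Apobec1 (1.70) was up and Apobec2 (-2.86) down, and of 22 cancer genes and cytokines linked to AID tumours 6 were up, with Myc at 2.23 and Ctnnb1 at 1.16, and 7 down. Trp53 was in neither list.

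**Figure D3:**
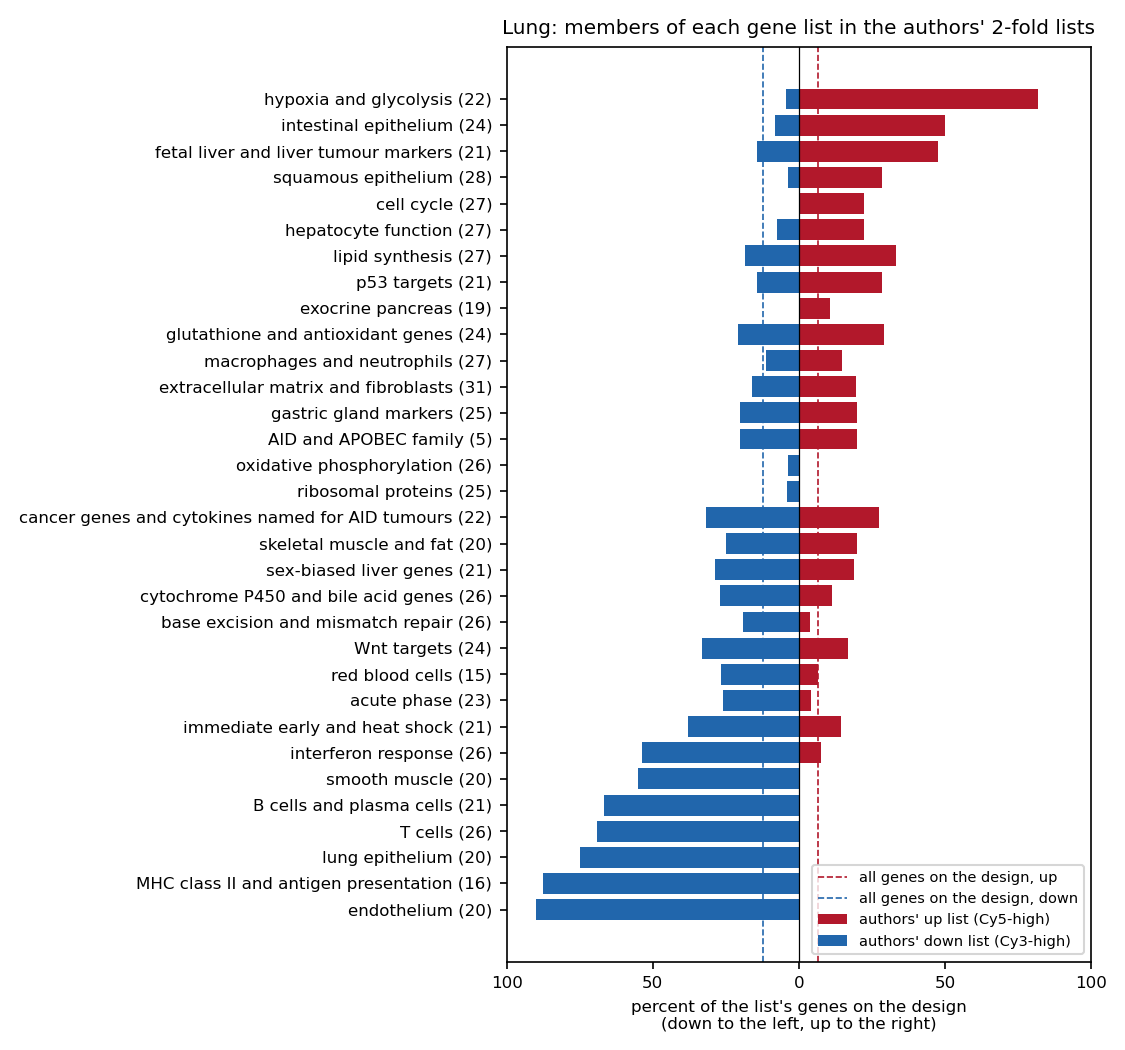
Percent of each gene list found in the lung up list (bars to the right) and down list (bars to the left) of the authors' deposited table, with the number of genes on the design in brackets; dashed lines give the shares of all genes, 6.71% up and 12.2% down. Hypoxia and glycolysis genes reach 81.8% up, and 18 of 20 endothelial genes are down.

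In the authors' deposited table the lung lists overlapped more in the same direction with the stomach lists than with the liver lists. Of 489 genes up at 2-fold in stomach, 240 were also up in lung, against 32.8 for independent lists over the genes on the design, and of 578 down in stomach, 217 were also down in lung, against 70.8. These numbers for independent lists were not matched on brightness. Whether part of an excess follows from which genes could be measured was not tested. Opposite directions were shared by 40 genes (stomach up, lung down, against 59.9) and 55 genes (stomach down, lung up, against 38.8). Of 98 genes up in liver, 43 (43.9%) were down in lung, where 12.2% of all genes were, and 17 were up, against 6.58 for independent lists. Of 38 genes down in liver, 13 were up in lung, against 2.55, and 5 were down, against 4.65. Genes in the lung up list of the authors' deposited table had a median log2 ratio of 0.23 on the stomach array and -0.004 on the liver array, and those in its down list -0.06 and 0.06. Over the listed genes, the lung ratio had a Pearson correlation of 0.38 with the stomach array (5175 genes) and -0.14 with the liver array (5177 genes).

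At 2-fold in all 3 organs, the authors' deposited table shared 3 genes in the up direction, Lypd8, Psrc1 and Sdcbp2, and 4 in the down direction, Cyp2f2, Rbp4, Selenbp1 and Selenbp2. No number for independent lists was worked out for these counts, and dye bias common to the arrays was not tested for them. Selenbp1 and Selenbp2 are close relatives whose probes could share transcripts, so they may be the same signal. Lypd8, Psrc1, Sdcbp2 and Selenbp2 are named here because the counts are small; they were chosen after their values were seen.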

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

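Opposite directions on the liver and stomach arrays drew attention to 4 genes and 1 gene list; with 1 array per organ, none of these differences was tested. The weighing of the list directions and of the lung lists used tests chosen after the results were seen, and the bounds for the probe comparison and the immune lists were set before their results were seen.

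Cd36 had a log2(Cy5/Cy3) of 1.28 in liver (SD 0.005 between 2 probes) and -2.33 in stomach (SD 0.93). Mup4 had -1.34 in liver and 1.21 in stomach, and Mup1 had -1.15 and 1.04 (SD 1.21 between 3 probes in stomach). Meg3, an imprinted noncoding RNA, had 1.06 in liver (SD 0.98 between 5 probes) and -1.06 in stomach (SD 0.87). Endothelial genes had a median of 0.12 in liver and -0.12 in stomach, and the stomach median turned to 0.08 with median centring alone.

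The headings of the authors' lists oppose the dye labels. A candidate explanation is that the labels of tumour and comparison tissue were exchanged. If a tumour tends to lose the products of its organ and to divide more, a tumour in Cy5 would show hepatocyte genes lower and fetal liver markers higher in liver Cy5, gastric gland markers lower and cell cycle genes higher in stomach Cy5, and lung epithelium genes lower in lung Cy5. All 5 of these lists lay that way, with medians of -0.28, 0.16, -1.07 and 0.84 and with 15 of 20 lung genes in the down list; the liver cell cycle list, left out of this tally, had a median of 0.05 (percentile 88.49), inside the central 95% of random lists. The hepatocyte median turned to 0.08 with median centring alone, and the premise about tumours was not itself tested, so the direction stays likely rather than settled.

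The ratios of liver and stomach correlated across genes, at 0.10. Probe-specific dye bias, shared because both arrays had the same orientation, may account for it: over 7788 genes with several probes, the correlation was 0.08 at the same probe and -0.01 between different probes of a gene, a ratio of -0.166 (95% interval from resampling genes -0.70 to 0.10), although different probes of a gene correlated at 0.27 within the liver array and 0.48 within the stomach array. A change in immune cells common to both tumours that shifts the list medians by 0.5 or more is argued against. The medians of the T cell, B cell and macrophage lists were at most 0.115 in size on either array. By the scanner software's ratios, T cells had 0.24 in stomach and -0.06 in liver, and macrophages and neutrophils 0.22 and 0.05. A smaller common change was not tested. Gene lists shifted to the same side on both arrays, such as glutathione and antioxidant genes (medians 0.26 and 0.48), were not tested for this bias, and the excess of shared 2-fold genes by the scanner software's ratios is open to the same bias.

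Lung and stomach shared 240 genes in the up lists of the authors' deposited table, against 32.8 for independent lists. Dye bias of probes common to all arrays is argued against as the cause: of the genes shared in either direction, 451 were measured on both arrays, and signed by list their median was 1.041 on the stomach array but 0.004 on the liver array of the same orientation, a ratio of 0.003 (95% interval from resampling genes -0.018 to 0.024). These genes were picked by their 2-fold stomach and lung ratios, which raises the stomach median. A bias of the lung and stomach arrays alone was not tested. The 217 genes shared in the down lists, against 70.8, were not weighed for the next explanation. For the genes shared up, stomach tumour RNA in the lung tumour sample stays open. It would make the lung signal in Cy5 beyond Cy3, from the authors' deposited table, a near constant part of the stomach signal in Cy5. Of the 240 genes, 120 lay within 2-fold of the median ratio, a share with a 95% interval of 0.433 to 0.562. An interval wholly under 0.5 would have argued against the explanation, and an interval wholly at 0.8 or more for it. The test cannot decide, because genes were picked as 2-fold up in both lists. That leaves out genes with little lung excess and can raise the share. Of 489 genes up in stomach, 40 were listed down in lung, and the genes not shared up were not weighed. An earlier test on gastric gland markers was dropped because most of them were Cy3-high on the stomach array. A shared gut-like programme of both tumours stays open as an untested biological hypothesis.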

How the results depend on the processing

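All alternatives here were planned before the data were examined. Counts of genes at 2-fold depended on some settings; the cause was not tested, except that the 3-fold threshold is stricter by construction. By the scanner software's ratios, 540 genes were Cy5-high and 420 Cy3-high in liver (39 and 18 in the report), 1092 and 1050 in stomach (221 and 359), and 114 and 134 on both arrays (1 and 4). With a normexp offset of 16, the counts were 72 and 57 in liver, 358 Cy5-high in stomach, and 3 and 9 on both. With median centring and no loess they were 110 and 7 in liver, 1017 and 235 in stomach, and 20 and 2 on both. At 3-fold they were 11 and 3 in liver, 40 and 146 in stomach, and 0 and 0 on both. The other settings left these counts within 1.5 times.

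The correlation of 0.10 between the arrays was 0.23 by the scanner software's ratios, 0.17 with offset 16, 0.45 with median centring, 0.13 with no filter on dim probes, and 0.08 each with no background correction (0.083), with both channels above background (0.083) and with the brightest probe per gene (0.083).

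Of 448 recomputed list medians, 407 lay within the interval from resampling the list's members, 33 moved outside it, and 8 more turned sign for lists outside the central range of random lists. All 8 came with median centring, which leaves the trend of the ratio with brightness in place. A further 35 medians of lists inside that range also turned sign, 15 with median centring and 20 under other settings. The 8 were hepatocyte function (0.0845) and cytochrome P450 and bile acid genes (0.0730) in liver, and T cells (-0.0487), endothelium (0.0807), exocrine pancreas (0.0784), hypoxia and glycolysis (0.32), immediate early and heat shock genes (0.17) and oxidative phosphorylation (0.44) in stomach. Of 483 recomputed values of named genes, 375 moved by less than the gene's measurement error and 108 by more, and no gene past 2-fold turned sign. Genes named as highest or lowest were picked with all probes and the scanner ratio past 2-fold in the same direction. Their signs thus could not turn by the scanner software's ratios, the brightest probe or the filter for both channels. Errors between probes could be wide: Sult2a2 in liver (SD 1.26) went from 2.13 to 3.36 by the scanner software's ratios and counted as less. The 4 genes Cy3-high on both arrays were each under 2-fold somewhere: in liver Slpi was -0.67 with no filter on dim probes, and with median centring Cyp2f2 was -0.94, Rbp4 -0.91 and Selenbp1 -0.75 (-0.36 in stomach), while Rbp4 was -0.81 in stomach with no background correction. The medians of the authors' lists for liver and stomach moved by less than the pooled SD between probes when the array values replaced the table's. No paired analysis was possible because each organ had 1 array and the result came from no test. Signal over background limits the dim genes, whose 2-fold differences the main setting mostly leaves uncounted.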

Other observations

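Some imprinted genes stood out on the liver array; they were chosen after their values were seen, and no list test was made. Beside Igf2 and H19, the noncoding RNAs of the imprinted region on chromosome 12 lay above 0 in liver and below 0 in stomach: Meg3 (1.06 and -1.06), Rian (0.73, SD 0.48 between 2 probes, and -0.52) and Mirg (0.88 and -0.70). Dlk1, a protein-coding gene of that region, had -0.04 in liver and -0.20 in stomach. Other imprinted genes were near 0 in liver: Peg3 -0.02, Plagl1 0.12, Cdkn1c 0.05, Grb10 0.04, Mest 0.01 and Sgce 0.13. In stomach all of these were below 0 as well: Peg3 -0.29, Plagl1 -0.37, Cdkn1c -1.69, Grb10 -0.25, Mest -0.10 and Sgce -0.13. Dcn had 0.64 in liver and -0.48 in stomach. The X-linked genes Bex1 and Bex4 had 1.33 and 1.68 in liver and -0.24 and -0.98 in stomach. Igf2 and H19 had -0.22 and -0.16 in stomach.

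The median ratios of genes on some chromosomes were shifted on the liver array, by small amounts. The median ratio of 981 genes on chromosome 15 was 0.05, and that of 827 genes on chromosome 16 was 0.03, both above the central 95% of 1000 random lists matched on brightness, as were chromosomes 13 (0.03), 18 (0.03) and 9 (0.02). The median of 1492 genes on chromosome 4 was -0.03 and that of 845 genes on chromosome 19 was -0.02, both below it. By the scanner software's ratios the values of 15, 16, 4 and 19 were 0.08, 0.05, -0.04 and -0.03 (0.076, 0.050, -0.043 and -0.035), again outside it, as were 13 and 18 (percentiles 98.1 and 98.9) but not 9 (73.3). On the stomach array chromosomes 15, 16, 4, 19, 18 and 9 lay within that range, and chromosome 13 (0.03) and chromosome 7 (-0.02) lay outside it. By the scanner software's ratios, chromosome 1 (0.045, percentile 99.4) lay outside it too, beside 13 (percentile 98.3) and 7 (percentile 0.1). These medians were looked at after the values were seen, over 20 chromosomes per array. The random lists were drawn gene by gene and do not keep neighbouring genes together. Whether the genes of a chromosome shift jointly was not tested.

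In the lung lists of the authors' deposited table, genes of the sex chromosomes differed between the mice. Xist, expressed from the inactive X chromosome of females, was 9.69-fold Cy5-high (log2 ratio 3.28), and the Y-linked genes Ddx3y and Uty had -4.25 and -2.35, while Eif2s3y and Kdm5d were in neither list. On the liver and stomach arrays, whose tissues came from the same mouse, Xist had -0.07 and -0.05 and Ddx3y 0.25 and -0.13, and Eif2s3y had 0.49 and 0.31. Lung genes with a difference between the sexes are therefore not separated from tumour genes in that comparison. The lung tissues came from different mice, transgenic and wild-type, so differences of animal or genotype are not separated from the tumour either, for any listed gene.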
